A study of Mus musculus with 12 samples.

How the data were processed

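Heart RNA was measured by paired-end sequencing of poly(A)-selected libraries in 12 mice, 3 in each of 4 groups. Per the labels, the groups were a sham operation or ischemia/reperfusion (I/R, 45 min of ischemia and 24 h of reperfusion), each with normal water or with vitamin B12 in the drinking water (B12, 50 mg/L for 7 days before surgery at an intake of about 4 mL per day). The authors deposited 1 table of gene expression in FPKM (fragments per kilobase of transcript, scaled to the library total) with 55487 genes, a column for each library and a column for each group mean. HISAT2, StringTie and the genome build mm10 are named in the labels, with no versions and no annotation release. The deposited FPKM behaved as that unit: FPKM multiplied by the annotated gene length summed to nearly the same value in every library (coefficient of variation 1.1%), while the plain FPKM sums varied more (4.2%). The group means were not used. Gene coordinates were taken from GENCODE M21, on the same mouse build, in which 55141 of the table's IDs were found. Where a symbol named several genes, the gene with the highest mean FPKM was used.

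The table gives no counts. Depth was therefore estimated from the steps between low FPKM values, which are spaced by 1 fragment per library. This gave 24.25 to 28.75 M fragments per library, with 83.0% to 88.9% of low values falling within 0.15 of a whole number of fragments. At this depth an FPKM of 1 in a transcript of 1500 nt stands for 36.4 to 43.1 fragments. These figures are estimates and cover counting error only.

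Values were analysed as log2(FPKM + 1). Genes with an FPKM of 1 or more in at least 3 libraries were tested, which left 13001 genes. All 12 libraries were fitted together with limma 3.58.1 in R 4.3.3, with a variance trend, and 5 contrasts were taken: I/R against Sham, I/R+B12 against I/R, Sham+B12 against Sham, I/R+B12 against Sham+B12, and the interaction, which is the I/R difference under B12 minus that on normal water. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called when the adjusted p was under 0.05. Tests were two-sided. The replicate numbers were not used as pairs, because same-number libraries of different groups did not resemble each other more than other pairs (mean r of 0.01 over 18 same-number pairs, after removing group means).

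Gene lists were fixed before the data were examined: 30 of pathways and 21 of cell type markers, of which 48 had at least 3 tested genes. They were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data. Camera compares the genes of a list with all other tested genes, so a list that passed as higher or lower was so relative to those genes. Calls within a list are also given with p-values adjusted over the list alone. List scores per library are mean log2 values of a list's tested genes, each centred over the 12 libraries.

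Named genes were chosen by a rule fixed before the data were examined. In each contrast these were the 12 largest increases and the 12 largest decreases among called genes whose libraries did not overlap between the groups, leaving out predicted genes. Where fewer than 5 genes were called, the 10 with the smallest p were named instead. The 4 members of each list with the smallest p were added, as were Nppa, Nppb, Myh6, Myh7, Sirt3, Prkaa1, Prkaa2, Mtr, Mmut, Tcn2, Cd320 and Ppargc1a. Some genes that this rule names are not reported here. The fit was tested on simulated data over 13001 genes, 200 of them changed. In the I/R against Sham contrast 56% of changes of 1 on the log2 scale and 96% of changes of 2 were recovered, and 5.7% of calls were false. In the I/R+B12 against Sham+B12 contrast the shares were 58%, 90% and 3.6%. The simulated noise was independent between genes and had the same spread in all groups, which the real libraries do not have. These shares therefore test the fit and need not hold for the real contrasts.

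The alternatives were other pseudocounts (0.1 and 0.5), no filter, a filter at an FPKM of 5, median-ratio scaling, quantile normalization, nuclear genes alone, the compared groups alone, no variance trend, a robust trend, library weights, a replicate block, and each library left out in turn. A fit without the libraries labelled Sham 3 and I/R 3 was added after the data were examined. Figures were drawn with matplotlib 3.10.9.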

Results

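Gene expression was measured in the hearts of 12 mice after a sham operation or ischemia/reperfusion (I/R), with normal water or vitamin B12 in the drinking water beforehand. Each of the 4 groups (Sham, Sham+B12, I/R and I/R+B12) had 3 libraries, at an estimated 24.25 to 28.75 M fragments each. Between 11490 and 12612 genes reached an FPKM of 1 per library. Differences below are log2 differences from limma with Benjamini-Hochberg adjusted p, and ± gives the SD of 3 libraries.

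The 6 libraries of mice labelled I/R did not form 1 group. The first principal component held 38.8% of the variance and the second 25.3%. The library labelled I/R 3 lay with the Sham libraries, and its nearest library was Sham 2 (r across genes of 0.982). It had 3.04 FPKM of Lcn2 and 9.1 of S100a9, against 278.64 and 706.17 in I/R 1. The library labelled Sham 3 carried high levels of injury genes: 210.48 FPKM of Lcn2 and 71.45 of Timp1, where Sham 1 had 5.01 and 1.66. It also had 3156.53 FPKM of Nppa, against 311.79 in Sham 1. Its score for the atrial cardiomyocyte list, which holds Nppa, was the highest of all libraries (0.6). Its nearest library was I/R+B12 1 (r of 0.969). The labels were kept as given in every comparison, and directions that involve Sham or I/R on normal water carry these 2 libraries. The 3 Sham+B12 libraries were the most alike (r of 0.98 to 0.984) and the 3 I/R+B12 libraries the least (0.936 to 0.947). The library I/R+B12 1 correlated more with the I/R libraries (mean r of 0.969) than with the others of its group (0.941). Its nearest library was I/R 1 (0.979).

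**Figure D1:**
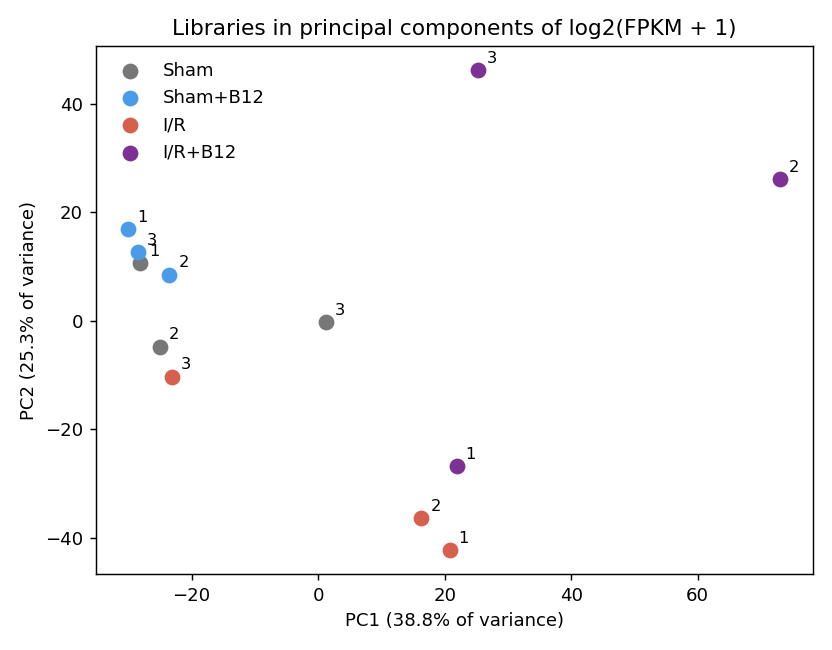
Principal components of log2(FPKM + 1) over 13001 genes, with 1 point per library, coloured by group and numbered by replicate (axes: component scores, with 38.8% and 25.3% of the variance). I/R 3 lies among the Sham and Sham+B12 libraries, Sham 3 lies apart from them, and I/R+B12 2 has the highest score on the first component (73).

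The comparison of I/R with sham in mice given B12 had called genes, unlike the other 4 contrasts. Among called genes whose libraries did not overlap between the groups, the largest increases included neutrophil, cytokine and acute phase genes. Only part of each of these gene lists was called over all genes. With an estimated correlation these lists did not pass camera. Saa3, an acute phase protein, rose by 6.52 (adjusted p 0.0446), Lcn2 by 6.09 (0.0491) and S100a9 by 6.03 (0.0485). The chemokines Cxcl2 (5.82), Cxcl1 (5.78), Cxcl3 (5.56) and Ccl2 (4.99) and the cytokine Il1b (4.71) rose too, as did Retnlg (5.13), Il1r2 (4.63), the stretch-responsive gene Ankrd2 (4.36) and Socs3 (4.30). The largest decreases were of Inmt (-3.37, adjusted p 0.0184), Cyp1a1 (-2.80, 0.0155), Abca8a (-2.80) and the clock output gene Dbp (-2.33), followed by Lrrc14b, Lmod3, Klhl38, Chaer1, Prelp, Cd300ld3, Pde4a and Cbr2 (between -2.22 and -1.91). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252, mm10) went from 5.96 ± 1.65 FPKM in Sham+B12 to a mean of 612 with an SD of 513 in I/R+B12. Inmt (ENSMUSG00000003477) went from 47.1 ± 4.35 to 4.6 ± 4.37. Cyp1a1 was higher in Sham+B12 than in Sham, though not called there, so its decrease starts from a level above that of Sham. In all, 1352 of 13001 genes were called, 882 higher and 470 lower, and 473 of them changed by 1 or more. The balance of directions depended on the fit: 1047 were higher and 851 lower with median-ratio scaling, 864 and 927 with quantile normalization, 1311 and 1771 with library weights, and 1346 and 2490 without I/R+B12 1. The libraries of the groups did not overlap in 32.4% of genes, where chance gives 10% on average over splits. Where no gene was called, this share was 22.4% in I/R against Sham, 23.2% in I/R+B12 against I/R and 10.5% in Sham+B12 against Sham. Genes are not independent, so the share of a single split can lie far from 10%.

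Of the cytokine, chemokine and receptor list 10 of 25 genes were called higher over all genes and 19 adjusted over the list alone (median 2.90), of the acute phase list 10 of 17 and 17 (median 2.46), of the neutrophil list 5 of 14 and 14 (median 3.37), and of the immediate early list 6 of 21 and 19 (median 1.49; Junb 2.86, Fosl2 1.86). With an estimated correlation none of these 4 lists passed camera (adjusted p 0.781 for each). With a pseudocount of 0.1 the cytokine and neutrophil medians were 4.55 and 5.31. The library I/R+B12 3 stood apart from its group, with a neutrophil score of 0.27 (2.03 and 3.79 in I/R+B12 1 and 2) and a cytokine score of -0.02 (1.56 and 2.57). Of the matrix list 5 of 28 genes were called higher (median 0.58, 0.25 with library weights and 1.15 with a filter at an FPKM of 5; scores of 0.73, 0.62 and -0.32 in I/R+B12 1, 2 and 3), among them Thbs1 (3.91), Adamts4 (2.99), Lox (2.27) and Mmp14 (1.86), and the list passed at the preset correlation (adjusted p 0.0103) but neither with an estimated one (adjusted p 0.781) nor with library weights (0.132). Hmox1 (2.67), Mt1 (2.46) and Txnrd1 (1.45) were among 4 of 25 antioxidant genes called higher, and that list did not pass (median 0.28, adjusted p 0.052). Of the complement list 4 of 13 genes were called lower (median -0.46; C4b -1.27, C3 -1.17, C1s1 -0.90, C1ra -0.59), of the ion channel list 3 of 21 (median -0.68, and -0.22 without I/R+B12 2; Scn4b -1.50, Kcnv2 -1.03, Abcc9 -0.84) and of the resident macrophage list 2 of 16 (median -0.75, and -1.18 without I/R+B12 1; Folr2 -1.16). With an estimated correlation these 3 lists did not pass (adjusted p 0.781 for each). The complement score was -0.06, -0.63 and -0.64 in I/R+B12 1, 2 and 3 (-0.17 to 0.13 in Sham+B12). The resident macrophage score was 0.27, -0.99 and -0.95 (-0.09 to 0.34 in Sham+B12). In both, I/R+B12 1 lay inside the Sham+B12 range. Cardiomyocyte markers had a median of -0.27 with none of 14 called (adjusted p 0.0428, and 0.781 with an estimated correlation; 0.102 with median-ratio scaling). Among genes of B12 and folate use, Mmut (-0.72, adjusted p 0.0353), which encodes the B12-dependent methylmalonyl-CoA mutase, Mmachc (-0.80), Shmt1 (-0.88) and Slc46a1 (-0.73) were called lower, and Mtr did not pass (-1.15, 0.053). These 4 were the only called genes among the 29 tested of the B12 and one-carbon list, which did not pass (median -0.17, adjusted p 0.0831, and 0.781 with an estimated correlation). Its score was -0.37 in I/R+B12 2, -0.16 in I/R+B12 3 and 0.06 in I/R+B12 1. Sirt5 was called lower (-0.98), and Sirt3 did not pass (-0.48, 0.0768). With camera at the preset correlation 17 of 48 lists passed, 9 higher and 8 lower, and with an estimated correlation none did. The number of called genes rested on single libraries: it was 0 without Sham+B12 1, 0 without Sham+B12 3, 32 without Sham+B12 2, 49 without I/R+B12 2 and 3836 without I/R+B12 1. Leaving out a library outside the comparison, which changes the variance estimate and its degrees of freedom, gave 641 without I/R 2, 830 without Sham 2, 875 without Sham 1, 901 without I/R 1, 1449 without Sham 3 and 1493 without I/R 3. The count at an unadjusted p under 0.05 was 4199 with all libraries and ran from 2909 without I/R+B12 2 to 5555 without I/R+B12 1.

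**Figure D2:**
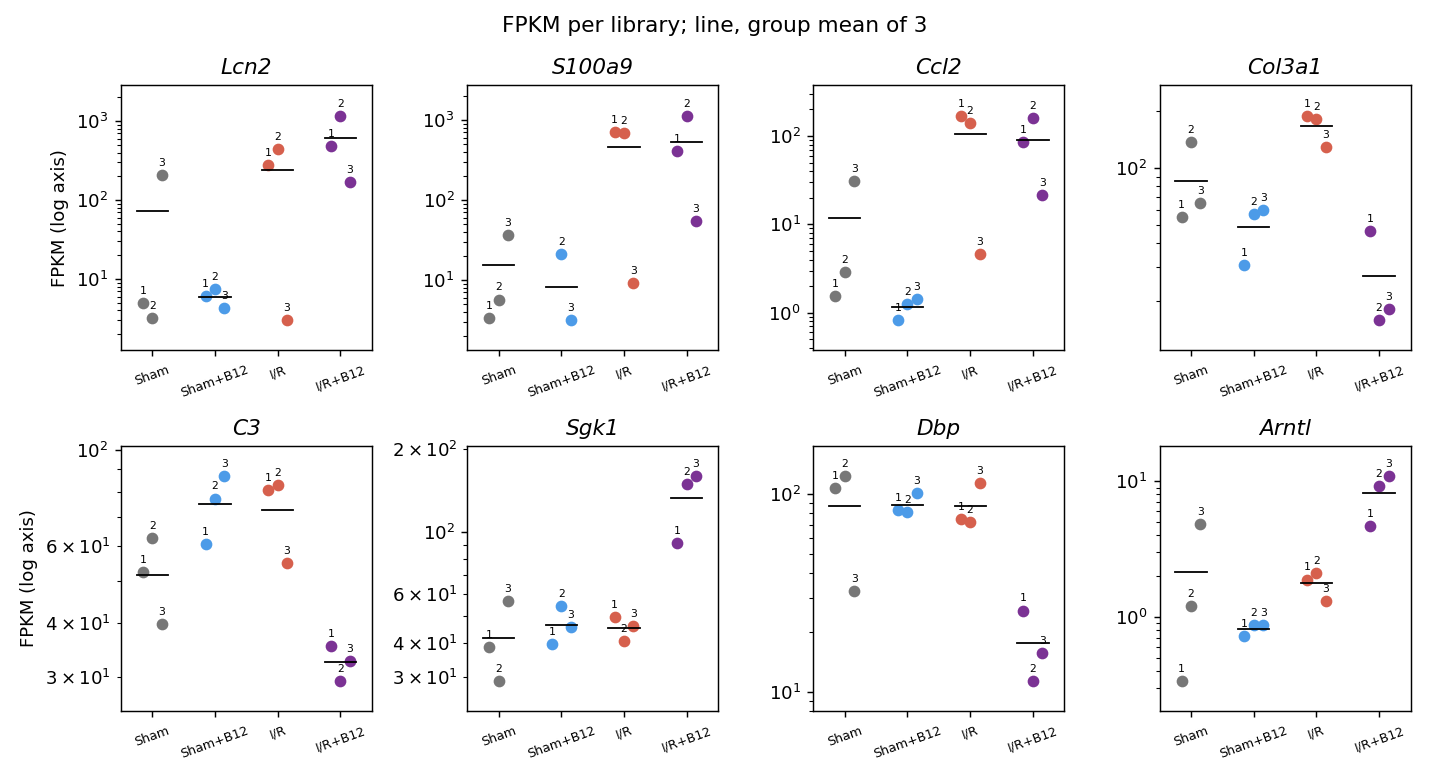
FPKM per library of 8 genes (log axis), with points numbered by replicate and a line at the mean of the 3 libraries of each group. S100a9 was listed at 0 in Sham+B12 1, which the log axis leaves out. Sgk1 and Arntl were higher, and C3 lower, in all 3 I/R+B12 libraries than in all 3 I/R libraries, while Lcn2 and Ccl2 were low in I/R 3.

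No gene was called in I/R against Sham on normal water. Cytokine genes had positive differences in 25 of 25 (median 1.74, and 2.59 without the library labelled I/R 3) and neutrophil genes in 14 of 14 (median 2.04, and 3.26 without it), with scores of -0.94 and -1.69 in I/R 3 where I/R 1 and 2 had 1.73 or more. The cytokine median ranged over the alternatives from 1.13 to 2.96 and the neutrophil median from 1.25 to 3.76. Neither list passed with an estimated correlation (adjusted p 0.673 and 0.676). Dnaja1, a heat shock cochaperone, had the smallest p (0.95, adjusted p 0.342), with 34.9 ± 3.30 FPKM in I/R and 17.5 ± 1.63 in Sham. It was followed by Tmem116 (-1.03), Gm37375 (2.63), Gm13166 (2.03), Gm17711 (-2.02), Ccl27b (-1.84), Lgals3bp (0.67), Nab1 (0.78), Gm50241 (1.55) and Gm26532 (1.01). S100a8 (3.88), S100a9 (4.04) and Ccl7 (3.31) had large mean differences with SEs of 1.65, 1.73 and 1.26. Adjusted over the list alone, 13 of 22 interferon-stimulated genes (median 0.82, and 0.50 without the library labelled Sham 3; Usp18 0.84, Rtp4 0.93, Zbp1 1.60, Irf7 0.87) and 11 of 18 cell cycle genes (median 0.62; Cdk1 1.36, Mcm3 0.82, Pcna 0.61, Mcm2 0.84) were higher. Neither list passed with an estimated correlation (adjusted p 0.419 for both). Differences were negative in 30 of 30 fatty acid genes (median -0.29; Hadh -0.38, Cpt1a -0.47) and in 25 of 26 sarcomere genes (median -0.28; Myh6 -0.62), with no member called over all genes or over the list alone, and neither list passed with an estimated correlation (adjusted p 0.419). With median-ratio scaling their medians were -0.45 and -0.44, and over the alternatives they ranged from -0.45 to -0.2 and from -0.44 to -0.23. Cardiomyocyte markers had negative differences in 14 of 14 (median -0.28, and -0.44 with median-ratio scaling) and inflammatory monocyte and macrophage markers positive ones in 16 of 16 (median 1.47, and 2.32 without the library labelled I/R 3). Their medians ranged over the alternatives from -0.44 to -0.16 and from 1.07 to 2.62. None of these markers was called, and their lists did not pass with an estimated correlation (adjusted p 0.419 and 0.673). Nppa (-0.94) and Nppb (0.51) did not pass (0.596 and 0.813), and the high Nppa of the library labelled Sham 3 enters the Sham mean. At an unadjusted p under 0.05 there were 1516 genes, 1381 of them higher, where 650 are given by chance. The median gene was 0.13 higher, and with median-ratio scaling, which removes that shift, 51% of 1198 such genes were lower. With camera 23 of 48 lists passed at the preset correlation and none with an estimated one. A single gene was called without Sham 1, Sham 3, Sham+B12 3 or I/R+B12 1, and 0 without any one of the other 8 libraries.

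The I/R differences on normal water and under B12, which share no library, had an r across genes of 0.45 (genes are not independent replicates). Of all 13001 genes 62.3% had the same direction in both, and of the 1352 genes called under B12 1145 (84.7%) had it: 817 of the 882 higher genes and 328 of the 470 lower ones. The median of the higher genes was 0.80 under B12 and 0.32 on normal water, and that of the lower genes -0.89 and -0.11. These genes were selected by their call under B12, which by itself favours larger medians there. The medians therefore cannot show whether the I/R difference was larger under B12. On normal water the median gene was at 0.13, which by itself raises agreement among higher genes and reduces it among lower ones. The shares therefore cannot show that decreases were less shared than increases.

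In I/R+B12 against I/R no gene was called. At camera's preset correlation alone, 16 lists ranked higher than the other genes and 7 lower. The median gene was at -0.21, so a list counted as higher need not have risen. The fatty acid list was counted as higher with a median of 0.01 and 15 of 30 differences negative. Among the lists that passed, the complement, interferon-stimulated and resident macrophage lists were lower and the glucocorticoid-responsive list higher (adjusted p 0.648 for each with an estimated correlation). The matrix list (adjusted p 0.929) and the inflammatory monocyte and macrophage list (0.672) did not pass. Of 28 matrix genes 8 were lower when adjusted over the list alone, and of 16 inflammatory monocyte and macrophage genes 3 were. The 10 genes with the smallest p all had an adjusted p of 0.0739: C1s1 (-1.09), C1ra (-0.93), Smad6 (1.14), Col3a1 (-2.73), Commd10 (-0.92), Ms4a4d (-1.01), Gm37375 (-2.67), Pcolce (-1.22), Lrrc2 (-1.06) and Col1a2 (-1.51). C1s1 (ENSMUSG00000038521, chromosome 6, 124530345 to 124542359, mm10) was at 21.8 ± 1.16 FPKM in I/R and 9.69 ± 0.0252 in I/R+B12. Col3a1 (ENSMUSG00000026043) was at 166 with an SD of 32.5 and at 26.8 ± 17.1. Adjusted over the list alone, 11 of 13 complement genes (median -0.93; C3 -1.12, Serping1 -0.69), 13 of 22 interferon-stimulated genes (median -0.79; Bst2 -1.64, Oasl2 -1.45), 11 of 16 resident macrophage genes (median -1.15; C1qa -1.26, Cx3cr1 -1.54), 10 of 18 cell cycle genes (median -0.67; Mcm2 -1.07, Top2a -1.24) and 6 of 14 fibroblast genes (median -0.44, and -0.19 with median-ratio scaling; Lum -1.23, Dcn -0.56) were lower, and 10 of 18 glucocorticoid-responsive genes were higher (median 1.50; Sgk1 1.50, Per1 1.47, Pdk4 2.46, Cdkn1a 3.10). None of these 6 lists passed with an estimated correlation (adjusted p 0.648 for each), and without I/R+B12 1 the interferon (0.138), cell cycle (0.226) and fibroblast (0.244) lists did not pass at the preset one either. The resident macrophage score of I/R+B12 1 (0.27) lay inside the range of the I/R libraries (0.15 to 0.62). Those of I/R+B12 2 and 3 were -0.99 and -0.95. Clock genes went both ways, with Dbp (-2.29) and Nr1d2 (-0.73) lower and Arntl (1.68) and Cry1 (0.94) higher. The neutrophil (0.84) and acute phase (0.87) medians were higher with B12, and with an estimated correlation neither list passed (adjusted p 0.648 for both). They were -0.40 and 0.24 without the library labelled I/R 3, and -0.04 and 0.50 without I/R+B12 2. The cytokine median was 0.63 (adjusted p 0.736 with an estimated correlation), and -0.27 without I/R 3 and -0.11 without I/R+B12 2. Of the other higher lists, the respiratory complexes III to V (0.10), sarcomere (0.10) and cardiomyocyte (0.16) lists had small medians (adjusted p 0.648 for each with an estimated correlation). Over the alternatives these medians ranged from 0 to 0.37, from -0.09 to 0.37 and from -0.02 to 0.43.

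In the same comparison no gene of B12 use or of energy sensing passed over all genes. Neither did the B12 and one-carbon list (median -0.26, adjusted p 0.798) or the AMPK and sirtuin list (-0.27, 0.54). Differences were negative in 22 of 29 and 15 of 17 genes of these lists. When adjusted over the list alone, 3 genes of the B12 and one-carbon list were lower and 0 of the AMPK and sirtuin list. The single differences included Slc46a1 (-0.83, adjusted p 0.0739), Mmut (-0.69, 0.0857), Mtr (-1.19, 0.0903), Nampt (-0.52, 0.0897) and Prkag2 (-0.89, 0.0952). Sirt3 was at 26.4 ± 3.52 FPKM in I/R and 24.2 ± 4.52 in I/R+B12, a difference within the spread of the libraries. At an unadjusted p under 0.05 there were 3711 genes, 3204 of them lower, where chance gives 650. The median gene was 0.21 lower, and with median-ratio scaling 49.8% of 3314 such genes were lower. With camera 23 of 48 lists passed at the preset correlation and none with an estimated one. The count of called genes was 4412 without I/R+B12 1, 68 without Sham 3, 2 without Sham 2 and 1 without I/R+B12 2, and 0 without any one of the other 8 libraries.

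**Figure D3:**
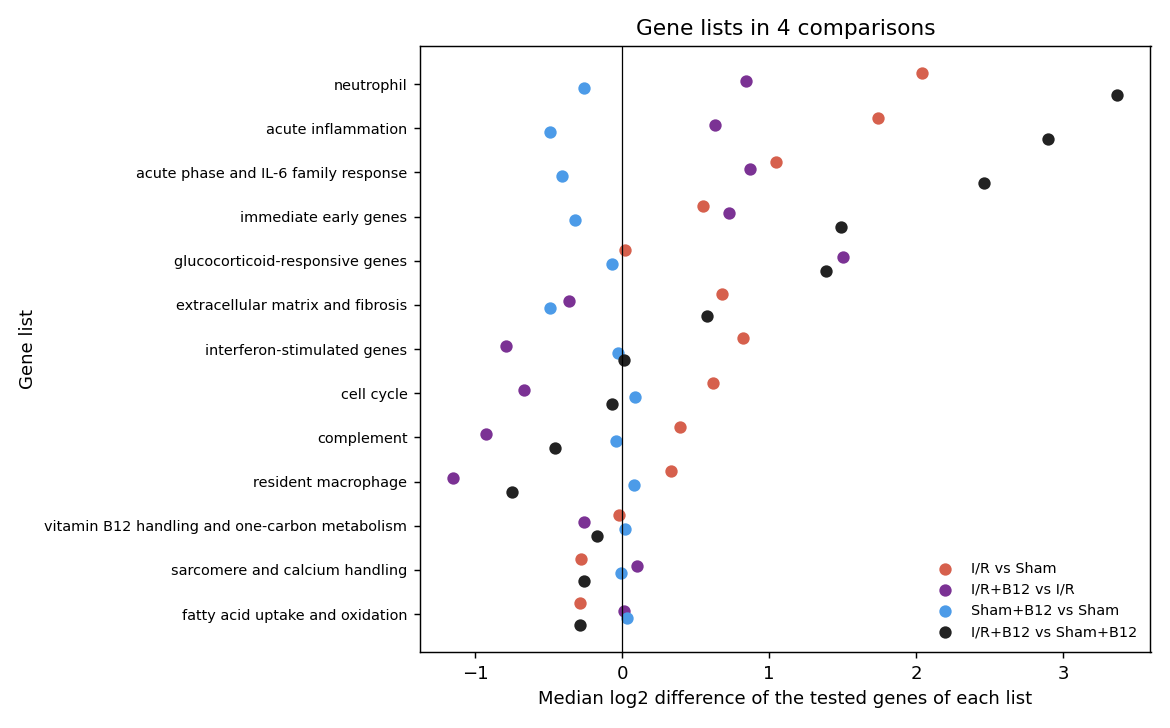
Median log2 difference of the tested genes of 13 lists in 4 comparisons (1 point per list and comparison; x axis in log2 units). Glucocorticoid-responsive genes had medians of 1.50 in I/R+B12 against I/R and 0.02 in I/R against Sham (0.39 without the library labelled Sham 3, 0.18 without I/R 3 and -0.38 without Sham 2). The neutrophil list had 3.37 in I/R+B12 against Sham+B12 and 2.04 in I/R against Sham. The latter was 3.26 without the library labelled I/R 3 and ranged from 1.25 to 3.76 over the alternatives.

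Whether B12 moved genes in the opposite direction to I/R was asked of all tested genes, since none was called in I/R against Sham. The I/R libraries enter both differences with opposite signs, so a negative relation arises without any effect. The covariance across genes was -0.035, and simulations in which I/R+B12 equalled I/R gave a mean of -0.05 (-0.059 to -0.042 in 100 runs). The simulated noise was independent between genes, which real libraries' is not, so these ranges are too narrow. Among the 1516 genes with an unadjusted p under 0.05 in I/R against Sham, 78.2% went the other way under B12, where simulation gave 68.6% (66.5% to 70.7%). Of these genes 1381 were higher in I/R, and the median difference of all tested genes was -0.21 in I/R+B12 against I/R. The simulations held no such general shift, which alone raises this share, so its excess cannot be read as B12 opposing I/R. When 1 I/R library was compared with I/R+B12 and the other 2 with Sham, the covariance was -0.047, -0.044 and 0.116 for I/R 1, I/R 2 and I/R 3.

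No gene was called for B12 in sham-operated mice. Cyp1a1 (2.22) had the smallest p (adjusted p 0.537). Cyp1a1 (ENSMUSG00000032315) was at 9.86 ± 4.18 FPKM in Sham+B12 and 1.31 ± 0.757 in Sham. Other genes with a small p were Gm17711 (-2.02), Gm16271 (1.97), Gm42959 (-2.73), Rev3l (-0.81), Gm15079 (-2.46), Cd209f (0.83), Dtnb (0.62) and Gm20498 (0.68). Matrix genes had negative differences in 26 of 28 (median -0.49; Mmp14 -0.90, Postn -0.57) with none called, and the list did not pass with an estimated correlation (adjusted p 0.899). The matrix score was 0.37 in the library labelled Sham 3, -0.73 and -0.39 in Sham 1 and 2 and -0.98 to -0.52 in Sham+B12, and without Sham 3 the median was -0.19 and the list did not pass (0.195). Mtr (0.25), Mmut (0.08) and Sirt3 (0.12) had an adjusted p of 0.999. At an unadjusted p under 0.05 there were 220 genes, where chance gives 650. There were 558 with the compared groups alone and 805 with library weights. The 4 groups share 1 variance estimate per gene, and the I/R+B12 libraries were the least alike. A count under 650 therefore does not argue for an absence of an effect. With camera 13 of 48 lists passed at the preset correlation and none with an estimated one (adjusted p 0.899 for each). Relative to the other genes 11 of them were higher (respiratory complex I with 29 of 33 positive and a median of 0.08) and the matrix and fibroblast lists lower. The median gene was at -0.07, and the hypoxia list was counted as higher with 10 positive and 10 negative differences. The count of called genes was 1 without Sham 1 and 0 without any one of the other 11 libraries.

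The interaction asked whether the I/R difference depended on B12. Complement genes were among those with the smallest p and none was called: C3 (-1.66), Smad6 (1.27), C1s1 (-1.17), Gm17711 (2.63), Cyp1a1 (-2.68), Morf4l1-ps1 (4.75), Pfkfb2 (-1.08), Gm17251 (2.14) and Gm33023 (-1.36) all had an adjusted p of 0.387. Adjusted over the list alone, 8 of 13 complement genes and 5 of 22 interferon-stimulated genes were lower. Neither list passed with an estimated correlation (adjusted p 0.893 for both), and without I/R+B12 1 the interferon list did not pass at the preset one (0.115). Dbp (-2.50), Arntl (2.19), Sgk1 (1.30), Mtr (-1.44) and Mmut (-0.78) did not pass (adjusted p 0.387). At an unadjusted p under 0.05 there were 1595 genes, 1152 of them lower, where chance gives 650. The median gene was at -0.14, and with median-ratio scaling, which centres the libraries, 49.2% of 1753 such genes were lower. The count of called genes was 1830 without I/R+B12 1, 1 without Sham 2, 1 without Sham 3 and 0 without any one of the other 9 libraries. With camera 14 of 48 lists passed at the preset correlation and none with an estimated one.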

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

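The tests on exchanged labels, depth and clock genes, and the split counts other than that of I/R+B12 against Sham+B12, were chosen or already determined after the results were seen. The I/R difference under B12 minus that on normal water was tested for each gene list, and 14 lists passed camera with the preset correlation. Their median log2 interactions were 1.46 for neutrophil genes, 1.33 for glucocorticoid-responsive genes, 1.06 for immediate early genes, 1.04 for fetal and cardiac stress genes, 0.96 for cytokines and their receptors, 0.94 for the acute phase list, 0.12 for antioxidant genes, 0.06 for respiratory complexes III to V and 0.05 for ribosomal proteins. They were -1.18 for resident macrophage genes, -1.02 for complement, -0.77 for interferon-stimulated genes, -0.68 for cell cycle genes and -0.59 for pericyte and smooth muscle genes. None passed with an estimated correlation (adjusted p 0.893 to 0.981), and no gene was called in the interaction by limma (1595 genes at an unadjusted p under 0.05). In all 25 fits the complement, glucocorticoid, immediate early and resident macrophage lists passed at the preset correlation, and each of the other 10 lists failed in at least 1 fit. Without the library labelled I/R 3 the neutrophil and cytokine medians were -0.09 and -0.05 and the neutrophil, cytokine, ribosomal and pericyte lists did not pass (adjusted p 0.19, 0.191, 0.431 and 0.0738), and the acute phase median was 0.42. Without I/R+B12 2 the fetal and cardiac stress median was 0.34 and that list did not pass (0.151), nor did the neutrophil (0.18), cytokine (0.184), ribosomal (0.44) and pericyte (0.0635) lists. Without I/R+B12 1 the interferon (0.115) and cell cycle (0.128) lists did not pass. The antioxidant median ranged over the alternatives from 0.03 to 0.31. The respiratory complexes III to V (-0.07 to 0.25) and ribosomal (-0.1 to 0.24) medians changed sign. Over the alternatives the neutrophil median ranged from -0.84 to 2.45, the cytokine median from -0.63 to 2.02, the acute phase median from 0.13 to 1.69 and the immediate early median from 0.38 to 1.41 (0.51 without I/R+B12 2, whose score was 1.94 against 0.40 and 0.20), while the complement median stayed between -1.24 and -0.81 and the glucocorticoid median between 0.65 and 1.83.

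The first pattern is that the library labelled I/R 3 sat at Sham levels in acute phase and neutrophil genes while the library labelled Sham 3 carried raised injury genes. The depth of these libraries is argued against, since 0 of the 2 lay outside the depth range of the other 10. An exchange of the 2 labels could give both, and other lists go with it or against it. The inflammatory monocyte and macrophage score was 0.37 in Sham 3 and -0.71 in I/R 3, and the matrix score 0.37 and -0.33. Sham 3 stayed below I/R 1 and I/R 2 in both (2.24 and 1.91, and 1.35 and 0.9). The acute phase score of Sham 3 was 1.72 above the highest of the other 5 sham-operated libraries, and that of I/R 3 (-1.22) lay inside their range (-1.39 to -1.18). Sham 3 (0.54) nonetheless stayed below I/R 1 (1.37) and I/R 2 (1.41), and its neutrophil score was -0.23 where theirs were 2.42 and 2.25. The interferon score of I/R 3 was 0.47, near I/R 1 and 2 (0.59 and 0.65) and above Sham 1 and 2 and Sham+B12 (-0.33 to 0.18), and that of Sham 3 was the lowest of the 12 (-0.60). The cell cycle score was 0.35 in I/R 3 (0.81 and 0.33 in I/R 1 and 2) and -0.50 in Sham 3, with at most 0.20 in the other sham-operated libraries. These 2 scores follow the labels as given, but they were low in I/R+B12 too (at most 0.07 and -0.09), so they do not mark every injured heart. The fatty acid score was 0.46 in Sham 3 and -0.11 in I/R 3 (-0.25 and -0.14 in I/R 1 and 2). The sarcomere scores were 0.2 and 0.1 (-0.25 and -0.32), and the cardiomyocyte scores 0.18 and 0.04 (-0.27 and -0.35). Sham 3 lay above I/R 1 and 2 in each, which goes against an exchange. So did I/R 3, which goes with it. With 2 libraries to compare against, an exchange and an uneven outcome of surgery cannot be told apart. Uneven surgery and the part of the heart sampled were not tested. Sham 3 correlated equally with Sham 1 and 2 and with I/R 1 and 2 (mean r of 0.962 for both).

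The second pattern is the higher level of glucocorticoid-responsive genes in I/R+B12 than in I/R. No gene was called there, and with an estimated correlation the list did not pass camera (adjusted p 0.648). Its scores were 0.4, 1.6 and 1.34 in I/R+B12 1, 2 and 3, and 0.13, 0.04 and -1.11 in I/R 1, 2 and 3. Scaling between libraries is argued against: with median-ratio scaling the list median was 1.75, where 1.50 was found without it. A candidate explanation is collection at another phase of the day or in another hormone state. Another phase of the day needs the clock genes to shift, which another hormone state need not do, so hormone state was not tested. The mean of Arntl, Npas2, Clock, Cry1 and Nfil3 minus that of Dbp, Tef, Hlf, Per3, Nr1d1 and Nr1d2 was 1.77 higher in I/R+B12 than in I/R, with no overlap (exact permutation p 0.1, two-sided, the smallest that 3 against 3 allows). The genes' directions were known when this was chosen. The labels give no collection times and the shift follows the group, so an effect of B12 in injured hearts, which the design names, and a more severe injury stay open and untested. Sham 3, which received neither B12 nor a labelled I/R, also had a higher value (-1.63) than the other 5 sham-operated libraries (-3.37 to -2.99).

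The third pattern is that 86.3% of the genes with an unadjusted p under 0.05 were lower in I/R+B12 than in I/R. With median-ratio scaling the share was 49.8%. That scaling centres the libraries, which brings the share near to an even split whatever its source, so scaling and a real shift cannot be told apart by it. A few abundant genes taking more of the library could also lower the rest. The 100 highest genes held 3.22 percentage points more in I/R+B12 (mean 43.8%, SD 2.97) than in I/R (40.6%, SD 3.14), within the spread of the libraries and between the bounds of 5 and 1 set before the test, which leaves it open. No biological explanation was tested.

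Other splits of the same libraries were fitted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. I/R+B12 against Sham+B12 had 1352 called genes and was the 1 split of 10 with as many, the highest of the others having 2. I/R against Sham had 0, so all 10 splits had as many, and the highest other had 90. That split exchanges the libraries labelled Sham 3 and I/R 3, and the 8 remaining splits had 0. I/R+B12 against I/R had 0, again matched by all 10, and the highest other had 351. In that split I/R+B12 1 is grouped with I/R 1 and I/R 2. The library I/R+B12 1 correlated more with the I/R libraries (mean r of 0.969) than with the others of its group (0.941). Sham+B12 against Sham had 0, the highest other had 0 and all 10 had as many. For the interaction 100 splits were drawn, 0 was observed, all 100 had as many and the highest had 22. Where 0 genes were observed every split has as many, so these counts decide nothing about chance.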

How the results depend on the processing

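The fit without the libraries labelled Sham 3 and I/R 3 was chosen after the data were examined, and because these libraries looked unlike their groups, so its counts favour a difference. In all 25 alternatives no named gene called in I/R+B12 against Sham+B12 changed direction, but many lost their call: of 1670 gene values in that comparison 1218 kept their side of the threshold, 446 no longer passed and 6 newly passed. Why calls were lost was not tested.

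The 1352 genes of I/R+B12 against Sham+B12 became 262 with no filter (220 shared; more genes are tested), 241 with the compared groups alone (206 shared; fewer residual degrees of freedom) and 3082 with library weights (1270 shared). Median-ratio scaling gave 1898, which is within 1.5 times, of which 1275 were shared. Leaving out 1 library gave 0 to 3836.

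For I/R against Sham, 0 genes became 2 with the compared groups alone, 4411 with library weights and 56 without Sham 3 and I/R 3, and 0 to 1 without 1 library. For I/R+B12 against I/R, 0 became 2 with median-ratio scaling, 1 with quantile normalization, 2 with the compared groups alone, 4325 with library weights and 5 without Sham 3 and I/R 3, and 0 to 4412 without 1 library. For Sham+B12 against Sham, 0 became 3 with no filter, and 0 to 1 without 1 library. For the interaction, 0 became 1 with no filter, 1838 with library weights and 2 without Sham 3 and I/R 3, and 0 to 1830 without 1 library. The weights ran from 0.17 (I/R+B12 1) to 9.83 (I/R 2) and their estimation stopped short of its tolerance, so those counts rest largely on single libraries. For the other changes the cause was not tested.

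The number of lists passing camera was 0 in each comparison with an estimated correlation. It went from 13 to 7 with no filter and to 21 with median-ratio scaling for Sham+B12 against Sham, from 23 to 10 with quantile normalization for I/R+B12 against I/R, from 14 to 9 with quantile normalization for the interaction, and from 17 to 11 with library weights for I/R+B12 against Sham+B12. Without 1 library it ran from 20 to 25 for I/R against Sham, 16 to 23 for I/R+B12 against I/R, 9 to 18 for Sham+B12 against Sham, 13 to 21 for I/R+B12 against Sham+B12 and 11 to 17 for the interaction.

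The covariance of the I/R and B12 differences (-0.035) was -0.077 and -0.046 with pseudocounts of 0.1 and 0.5, -0.137 with library weights and -0.072 without Sham 3 and I/R 3. Without 1 library it ran from -0.085 to 0.002, and it turned positive (0.002) without I/R+B12 3. The cause was not tested. The compared groups alone give no other fit for the interaction, which uses all 4 groups. No paired analysis was possible because the replicate numbers do not pair the mice. A fit with the replicate number as a block gave 1057 genes for I/R+B12 against Sham+B12 and 0 in the other comparisons. At the estimated depth, counting error is small for genes at an FPKM of 1 or more, and the spread between libraries sets the limits.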

Other observations

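Sex-linked genes agreed across libraries: Ddx3y was at 5.31 to 12.53 FPKM in all 12, which gives no sign of a library from an animal of the other sex and cannot separate libraries of 1 sex. The library I/R+B12 2 differed from its group in several genes, with 839.15 FPKM of Saa3 against 115.68 and 17.06, 74.74 of Il6 against 8.68 and 7.84, and 2038.81 of Nppb against 329.25 and 219.96. Its platelet list score was 2.32, against -0.09 and -1.26.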
